A study of Xenopus laevis with 6 samples.

How the data were processed

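Both blastomeres of 2-cell Xenopus laevis embryos received triple FLAG-tagged β-catenin (500 pg in the labels' wording, at a level said not to alter the phenotype), and whole embryos were collected at stage 11.5. Per the labels' protocols, chromatin was crosslinked with formaldehyde, sonicated in pools of 100 embryos and precipitated with a FLAG antibody, while the series' design text speaks of about 500 embryos fixed per pool. The 6 samples are 3 ChIP libraries and 3 inputs. Replicate numbers come from the labels. The inputs entered only through the authors' peak calling, in which each ChIP library was paired with 1 input, per the names of the deposited lists.

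Per the submitters' processing notes, Bowtie2, SAMtools, MACS, HOMER and bedtools were used; their versions, roles and settings are not given in the sources used here, and neither is the genome build. The deposited lists are 1 MACS and 1 HOMER list per replicate, called on single libraries and not on pooled ones per the same names, and 1 combined list. The value beside each peak in the deposited lists is a score that the authors' caller gave and that no file header names, so it was used only to describe, rank or filter peaks within its own list. MACS scores began at 50 in each list and reached 3100 or slightly more, 4 peaks of replicate 1 and 2 of replicate 3 sharing the value 3100. HOMER scores were whole numbers beginning at 12, 14 and 9 in replicates 1, 2 and 3, and HOMER peaks had a near-constant width of 172, 290 and 246 bp. Whether HOMER scores were scaled to depth is not known. A stricter threshold in one list than in another moves its length, so peak numbers cannot be read as amounts of binding. In the replicate 1 HOMER list, 1 interval had a width of 0 bp and was kept. The scores in the combined list were compared with those of the MACS lists.

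Overlap meant at least 1 shared bp. Where MACS peaks were split by HOMER calls, a HOMER peak in any of the 3 replicates counted unless the same replicate is named. Overlap shares carry 95% Wilson intervals, which cover counting error only. Each of the 30 ordered pairs of lists was compared with 1000 random placements of the peaks within their own chromosome or scaffold, whose length was taken as the farthest peak end in any list. The test was 2-sided. Scores of peaks found in both other replicates or in neither were compared by the difference of medians, with 100000 resamples in each of 6 lists. The combined list was rebuilt by intersecting the 6 lists, and its overlapping intervals were merged into regions. L and S densities were compared over the 9 chromosome pairs with an exact 2-sided sign-flip permutation test (512 sign patterns, smallest p 0.00391) in a family of 12 lists and subsets. Numbers per chromosome were compared with each chromosome's share of the summed extents by a 2-sided exact binomial test over 18 chromosomes. Benjamini-Hochberg adjustment was made within each family, with a threshold of 0.05. Neighbouring peaks are not independent, and tests over peaks treat them as if they were.

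The comparisons of peak number, overlap, the combined list and scores were chosen before the data were examined. The L and S densities, numbers per chromosome, spacing of regions and HOMER calls by sharing class were added afterwards. Regions named in the text are the 10 common regions with the best mean rank of the MACS score over the 3 replicates, the rule fixed beforehand for lists without gene names; any other region named was chosen after its values were seen. Alternatives were a minimum overlap of 50% of both intervals, centres within 200 bp, the better 50% of each list by score, equal list lengths, only sequences with 10 or more peaks, and leaving out each replicate. For L and S density, each chromosome pair was also left out in turn.

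Gene positions, 10 gene lists, 20 sequence motifs and pairs of L and S genes had also been fixed, but a genome of the lists' build was not used here. A gene table of assembly version 10.1 was not applied, since on all 18 chromosomes the last peak lay 4.73% to 20.7% before the last gene in that table. No column of per-sample values was left out.

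The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, matplotlib 3.10.9 and, for a check of overlaps, bedtools 2.31.1. Overlap counts were checked against bedtools and differed in 0 of 30 pairs. On simulated lists with planted overlaps, shares were recovered to within 0.564 percentage points, and a planted log2 L to S excess of 0.25 over 9 pairs was recovered as 0.26.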

Results

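β-catenin is the transcriptional effector of canonical Wnt signalling; it does not bind DNA itself and is brought to chromatin by partners such as the TCF/LEF factors. The series addressed where β-catenin lies on the genome during gastrulation of Xenopus laevis, a frog whose allotetraploid genome is arranged in 9 pairs of L and S chromosomes. Chromatin from whole embryos at stage 11.5 was sequenced after immunoprecipitation of injected FLAG-tagged β-catenin in 3 replicates, and 3 input libraries were made in parallel. The values analysed were peak positions and scores from 2 peak callers, MACS and HOMER, run on each replicate, and 1 list of regions common to them. Sequencing depth is unknown, because the peak lists carry no read totals, and the input libraries have no values of their own here. The labels do not say whether the replicates came from separate clutches, so the spread between them may be technical.

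Enrichment of FLAG-tagged β-catenin called by both callers in all 3 replicates was found at 768 separate regions. Of these, 717 lay on the 18 chromosomes and 51 on unplaced scaffolds. No library from embryos without the tagged protein is in the series, so the regions are peak calls and not proven binding sites. The region with the best mean MACS rank lay on chromosome 1S at 16874036 to 16874535, and ranked 11, 11 and 89 by the authors' MACS score in replicates 1, 2 and 3. A pair of regions on chromosome 8L, at 24899856 to 24900355 and at 24925951 to 24926450, ranked next. The latter held the highest MACS score of replicate 2, at 3106, and ranked 46 in replicate 1 and 96 in replicate 3. The fourth region, on chromosome 1L at 158721425 to 158721924, ranked 12, 21 and 113 in the MACS lists of replicates 1, 2 and 3 and had HOMER scores of 100, 147 and 48.

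The other 6 of the 10 best-ranked regions were on chromosome 1S at 1824115 to 1824614, 68388673 to 68389172 and 131139536 to 131140035, on 1L at 18525031 to 18525530, on 7S at 16905412 to 16905911 and on 7L at 21863777 to 21864276. Among these, the region at 1824115 on 1S had the highest HOMER scores of the 10 in every replicate, at 146, 153 and 58. Each of the 10 was a single 500 bp interval. Coordinates are those of the deposited lists, whose genome build is not given in the sources used here, and nearest genes were therefore not assigned. Scores were not on one scale across lists, so a score is to be read only against others of its own list.

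The common list held 855 intervals, and every one overlapped a peak of each of the 6 per-replicate lists. Rebuilding the stretches of sequence shared by all 6 lists also gave 855 pieces. All 851 common intervals of 500 bp were centred within 1 bp of such a piece, and all 855 scores equalled the mean of the 3 overlapping MACS scores to within 0.01. Merging overlapping intervals left the 768 regions. Peaks overlapping a common interval made up 7.50%, 2.98% and 2.29% of the MACS lists of replicates 1, 2 and 3, and 8.30%, 7.44% and 18.2% of the HOMER lists. The number depended on replicate 3: 2744 intervals were shared by the 4 lists of replicates 1 and 2, and 1593 by the 5 lists other than the replicate 3 MACS list. The 3 MACS lists alone shared 2137 stretches and the 3 HOMER lists alone 1797.

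Within the 768 regions, scores of different replicates were correlated. Across regions, Spearman's rho for MACS scores was 0.583 between replicates 1 and 2, 0.393 between 1 and 3 and 0.559 between 2 and 3. For HOMER scores it was 0.650, 0.575 and 0.653 in the same order. Regions are not independent replicates, and no test was made.

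Common regions were found on all 18 chromosomes, in a comparison added after the lists were examined, at 0.286 per Mb overall. Chromosome 7L held the most for its length, 59 regions or 0.465 per Mb (95% interval 0.364 to 0.592), 1.63-fold the number given by its share of the summed chromosome extents (exact binomial p = 0.000313, adjusted p = 0.00564 over 18 chromosomes). Chromosome 2S held the fewest for its length, 28 regions or 0.175 per Mb (0.122 to 0.251), and did not pass the adjusted threshold (exact binomial adjusted p = 0.0515). Chromosome 9_10L, with 49 regions or 0.416 per Mb, also did not pass (exact binomial adjusted p = 0.0611). Neighbouring regions are not independent, and with regions within 50 kb counted once 7L held 41 groups, 1.45-fold its share, which did not pass the adjusted threshold (exact binomial p = 0.0197, adjusted p = 0.178).

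**Figure D1:**
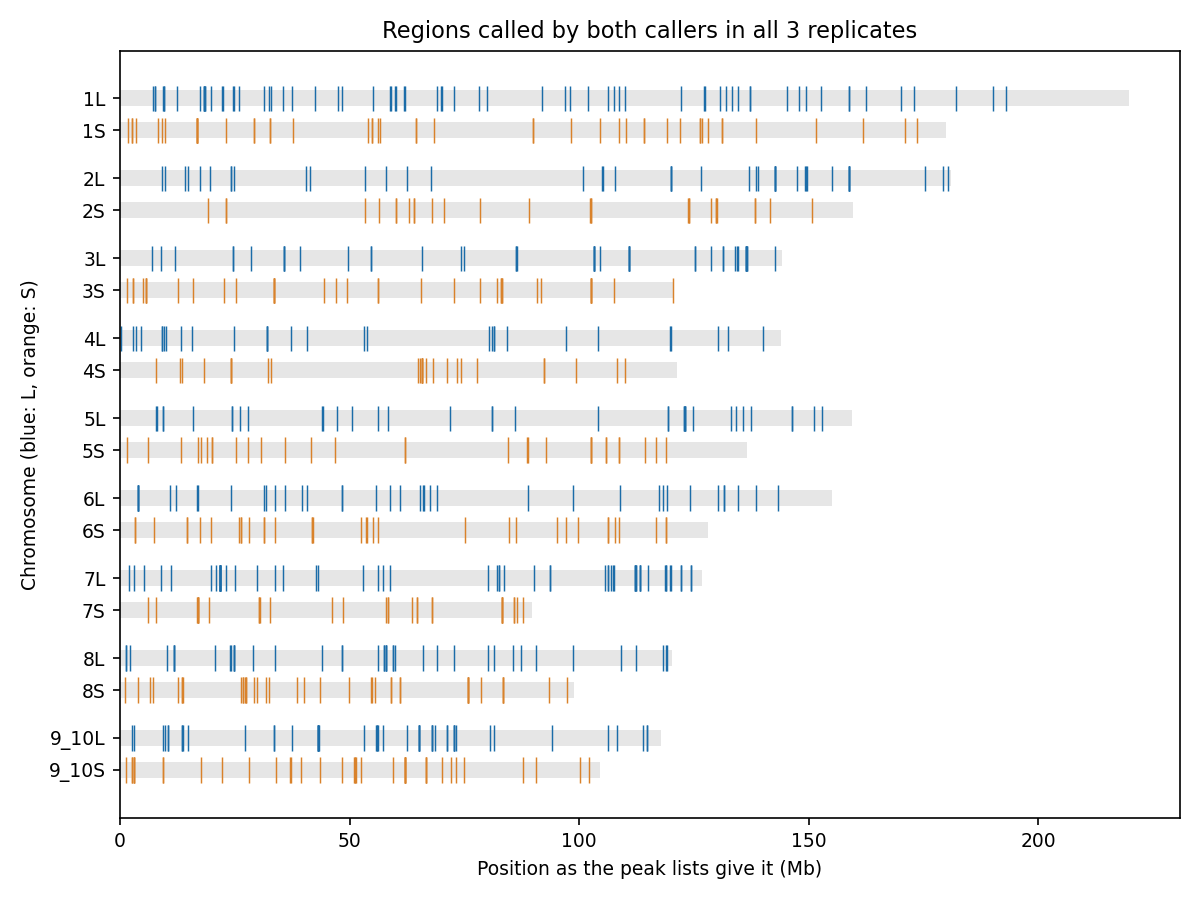
Positions in Mb of the common regions (vertical ticks) on each L (blue) and S (orange) chromosome, with grey bars drawn to the farthest peak end in any list. The 717 placed regions lie on all 18 chromosomes, with 59 on 7L and 28 on 2S.

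The copies of the genome were compared by peak density over the 9 L and S chromosome pairs, a comparison added after the lists were examined. HOMER peaks were denser on L chromosomes in every replicate, with a mean log2 ratio of L to S density of 0.22 ± 0.12 in replicate 1, 0.23 ± 0.09 in replicate 2 and 0.23 ± 0.20 in replicate 3 (SD over 9 pairs). L was the denser member in 9, 9 and 8 of the 9 pairs (exact sign-flip adjusted p = 0.00937, 0.00937 and 0.0234). The units of this test are the 9 pairs within 1 list, so p describes consistency across chromosomes and not the spread between embryos. MACS peaks were denser on L in replicate 1, at 0.13 ± 0.08 and in 9 of 9 pairs, and denser on S in replicate 3, at -0.22 ± 0.08 and in 9 of 9 pairs (exact adjusted p = 0.00937 for both). In replicate 2 the MACS ratio was -0.07 ± 0.08, with S denser in 7 of 9 pairs (exact adjusted p = 0.0521), and -0.0060 in the better 50% of that list by score (exact adjusted p = 0.887). The common regions stood at 407 on L and 310 on S chromosomes, a mean log2 ratio of 0.10 ± 0.24 that did not pass the test (exact adjusted p = 0.286).

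The callers differed within a replicate. HOMER minus MACS log2 ratios averaged 0.09 ± 0.09 in replicate 1, 0.30 ± 0.11 in replicate 2 and 0.45 ± 0.21 in replicate 3, and the HOMER ratio was higher in 8, 9 and 9 of the 9 pairs (exact sign-flip p = 0.0195, 0.00391 and 0.00391, adjusted p = 0.0195, 0.00586 and 0.00586 over the 3 replicates). HOMER peaks found in all 3 replicates were denser on L, at 0.22 ± 0.15 (exact adjusted p = 0.0134), whereas the MACS peaks found in all 3 gave 0.01 ± 0.11 (exact adjusted p = 0.836). Chromosome lengths were taken as the farthest peak end in any list, and differences in mappability between L and S chromosomes were not measured.

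**Figure D2:**
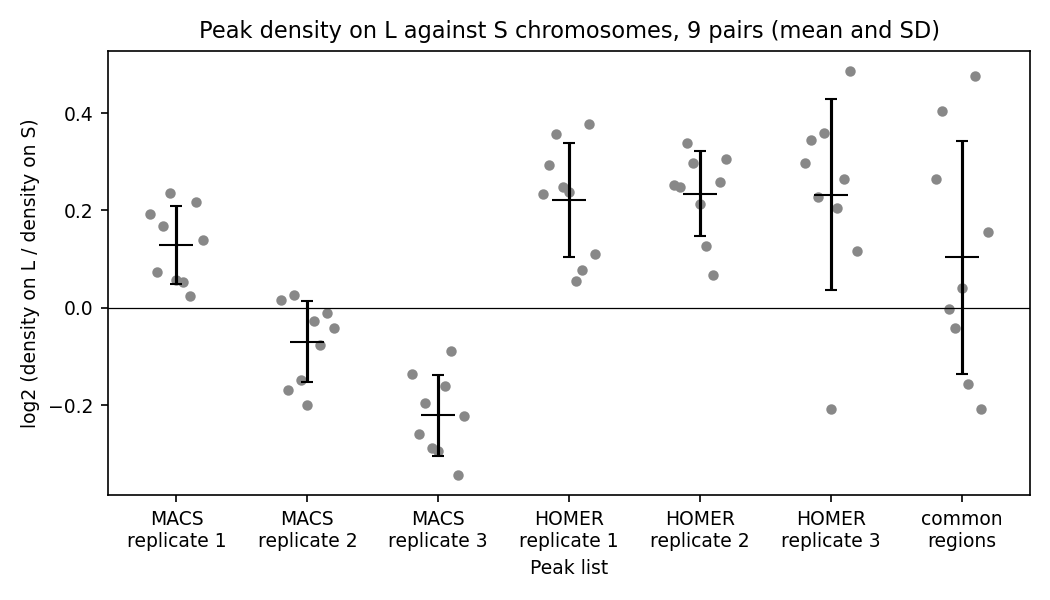
Log2 ratio of peak density on the L chromosome to that on its S partner, for each of 9 pairs (grey points), with the mean (horizontal line) and SD (bars) per list. Mean ratios lie between 0.22 and 0.23 in the HOMER lists and between -0.22 and 0.13 in the MACS lists.

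The number of peaks called per replicate varied widely. MACS gave 10351, 27402 and 40056 peaks in replicates 1, 2 and 3, a mean of 25936 ± 14907 (SD, n = 3), covering 3.88, 9.36 and 10.7 Mb. HOMER gave 9258, 10317 and 4218 peaks, a mean of 7931 ± 3259 (SD, n = 3), covering 1.59, 2.98 and 1.03 Mb. Replicate 3 thus had the most MACS peaks and the fewest HOMER peaks. Unplaced scaffolds held 8.71%, 10.7% and 9.17% of the MACS peaks and 9.27%, 7.12% and 7.16% of the HOMER peaks.

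Peaks recurred between replicates far more often than randomly placed peaks. Of the replicate 1 MACS peaks, 46.0% (95% Wilson interval 45.1 to 47.0) overlapped a replicate 2 MACS peak, against 1.19% after random placement, and 21.9% (21.1 to 22.7) overlapped one of replicate 3. Of the replicate 2 MACS peaks, 42.5% were found in replicate 3 and 18.8% in replicate 1. The much longer replicate 3 list had 30.1% of its peaks in replicate 2 and 6.26% in replicate 1. For HOMER, 65.6% (64.1 to 67.0) of the replicate 3 peaks were found in replicate 2 and 48.5% in replicate 1. Of the replicate 1 HOMER peaks 45.1% were found in replicate 2, and of the replicate 2 peaks 26.8% in replicate 3. These shares depend on list length. With the 4218 best-scoring HOMER peaks of each list, 54.5% of replicate 1 peaks were in replicate 2 and 42.7% in replicate 3. Of the replicate 2 HOMER peaks, 54.1% were then in replicate 3. With the 10351 best-scoring MACS peaks of each list, 34.9% of replicate 1 peaks were in replicate 2 and 11.4% in replicate 3. Of the replicate 2 MACS peaks, 42.4% were then in replicate 3. All 30 ordered comparisons between lists lay above every random placement (permutation p = 0.002 each, the smallest that 1000 placements could give 2-sided, adjusted p = 0.002). The 30 include comparisons of the 2 callers within a replicate, which rest on the same library and do not measure recurrence. Intervals cover counting error only, and random placement ignored mappability.

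Regions recurring in all 3 replicates were counted from each list, so the counts within a caller describe largely the same regions. For MACS, 1880, 1912 and 2087 peaks of replicates 1, 2 and 3 were found in both other replicates, or 18.2%, 6.98% and 5.21% of each list. For HOMER the numbers were 1798, 1839 and 1806, or 19.4%, 17.8% and 42.8%. Percentages of a list depend on its length, and the replicate 3 HOMER list was the shortest. Peaks seen in no other replicate made up 68.8% of the replicate 3 MACS list and 28.8% of the replicate 3 HOMER list.

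**Figure D3:**
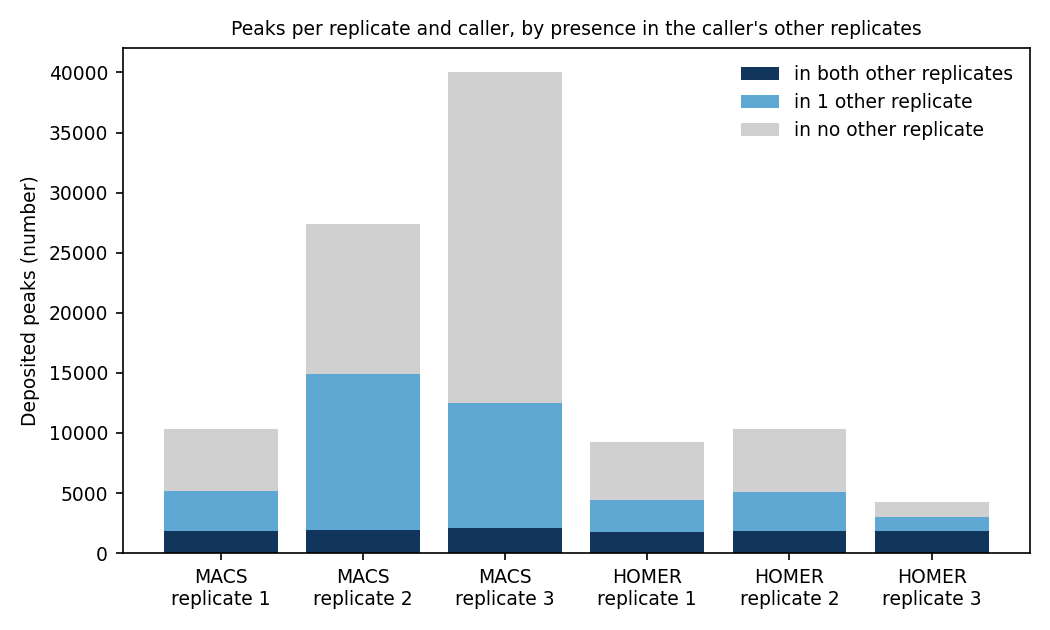
Number of deposited peaks per caller and replicate, split by whether each peak overlapped peaks of the same caller in both (dark blue), 1 (light blue) or none (grey) of the other replicates. The dark part holds 1798 to 2087 peaks in every list, while whole lists run from 4218 to 40056.

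Overlap between the callers, which describes how the lists were made and not a biological difference, varied between replicates. With at least 1 shared bp, HOMER peaks were found in the MACS list of their own replicate in 56.6% (95% Wilson interval 55.6 to 57.6), 52.6% (51.7 to 53.6) and 30.9% (29.5 to 32.3) of cases for replicates 1, 2 and 3. In the other direction, 50.9%, 21.8% and 3.62% of the MACS peaks had a HOMER peak of the same replicate. The replicate 3 HOMER peaks lay more often in the MACS lists of replicate 1, at 58.4% (56.9 to 59.9), and of replicate 2, at 59.3% (57.8 to 60.8), than in their own. With centres within 200 bp, the replicate 3 HOMER peaks were found in the MACS lists of replicates 1, 2 and 3 at 56.2%, 56.5% and 30.3%. A rule of 50% of both intervals gave other orders, but it also depends on peak width. HOMER peaks of near-constant width cannot share 50% of a much wider MACS peak. Median MACS widths were 345, 263 and 196 bp in replicates 1, 2 and 3. With at least 50% of both intervals shared, 16.5%, 28.7% and 19.2% of the HOMER peaks of replicates 1, 2 and 3 were found in their own MACS list, and the replicate 3 HOMER peaks were found in the MACS lists of replicates 1 and 2 at 20.2% and 15.8%. Under that rule the replicate 2 HOMER peaks also lay more often in the MACS list of replicate 1, at 30.5% (29.6 to 31.4), than in their own.

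**Figure D4:**
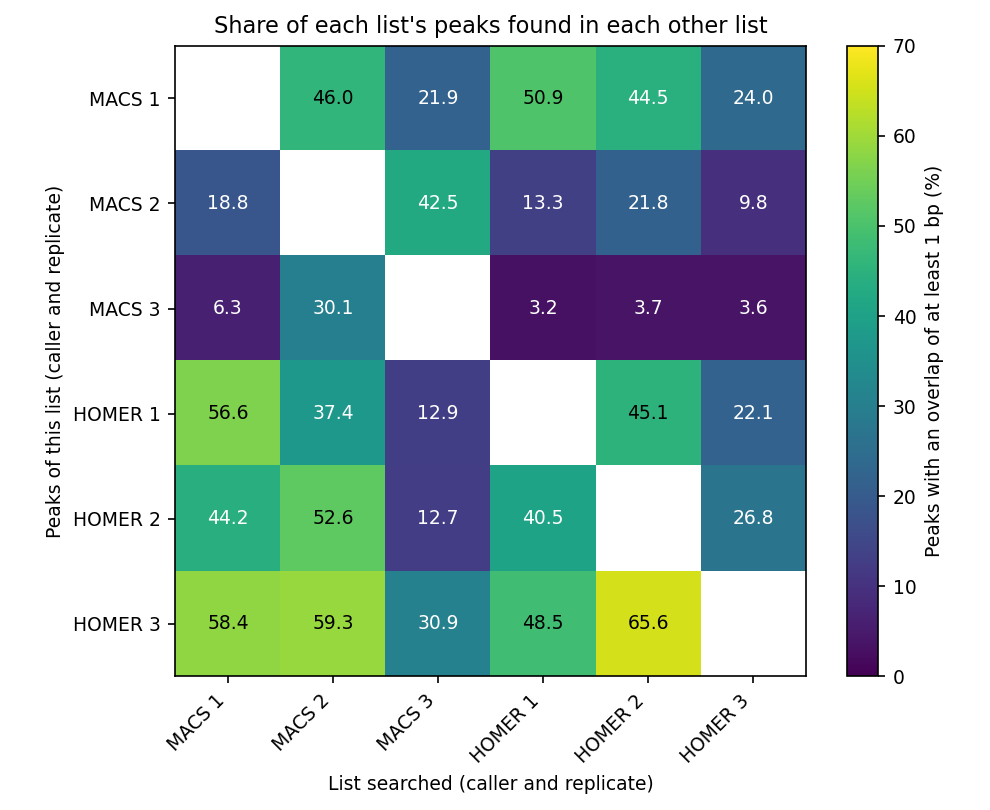
Percentage of the peaks of each list (vertical axis) that overlapped a peak of each other list (horizontal axis) by at least 1 bp, on a colour scale from 0 to 70, which holds for that overlap rule. The replicate 3 HOMER list overlapped its own MACS list at 30.9% and the MACS lists of replicates 1 and 2 at 58.4% and 59.3%.

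Among the highest-scoring 10% of MACS peaks, 93.5% had a HOMER peak of the same replicate in replicate 1, 69.3% in replicate 2 and 7.16% in replicate 3. HOMER calls at the replicate 2 MACS peaks, a comparison added after the lists were examined, depended on which replicate shared the peak. Of the 3248 peaks shared with replicate 1 alone, 88.3% (95% Wilson interval 87.1 to 89.4) had a HOMER peak in any replicate, and 82.4% (81.1 to 83.7) had one in replicate 2. Of the 9746 shared with replicate 3 alone, 3.66% (3.31 to 4.05) had a HOMER peak in any replicate, and 136 had one in replicate 2. Of the 12496 peaks in neither other MACS list, 17.2% (16.6 to 17.9) had a HOMER peak in any replicate. Of the 1912 peaks shared with both, 65.5% (63.4 to 67.6) did. In the replicate 3 MACS list, a HOMER peak in any replicate was found for 0.472% of the 27562 peaks in no other MACS list. The share was 3.58% for peaks shared with replicate 2 alone, 18.1% with replicate 1 alone and 65.2% with both. Replicate 1 MACS peaks shared with replicate 3 alone had one in 14.4%, against 50.4% of those in no other MACS list. Few HOMER calls were thus not limited to peaks shared by replicates 2 and 3.

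**Figure D5:**
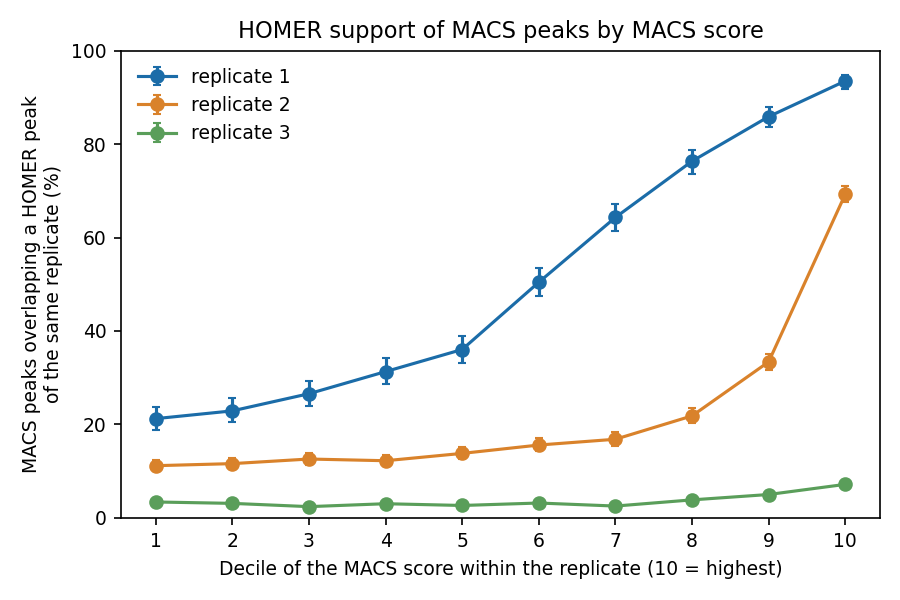
Percentage of MACS peaks with a HOMER peak of the same replicate, by decile of the MACS score within each replicate, with 95% Wilson intervals. In the highest decile it reaches 93.5% in replicate 1 and 69.3% in replicate 2, against 7.16% in replicate 3.

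Peaks that recurred had higher scores than peaks seen once, in each of the 6 lists. The median MACS score was 129 for replicate 1 peaks found in both other replicates and 62.4 for those found in neither. In replicate 2 the medians were 273 and 60.2, and in replicate 3 they were 98.3 and 63.2. Median HOMER scores were 34 and 15 in replicate 1, 43 and 17 in replicate 2, and 13 and 9 in replicate 3. The size of the difference depended on the overlap rule and on how recurrence was counted. For MACS peaks found in at least 1 other replicate it was 27.5 in replicate 2, against 212 for peaks found in both, and with 50% of both intervals shared it was 123 in replicate 3, against 35.2. Every difference passed a 2-sided permutation test over peaks (p = 1e-05 and adjusted p = 1e-05, the smallest that 100000 resamples could give). Peaks are not independent replicates, so this test describes each list and not the spread between embryos.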

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

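The alternatives for L and S density, spacing and HOMER calls by sharing class, for HOMER peaks in their own MACS list, and the one without the replicate 3 MACS list, were chosen after the data were examined. All 72 recomputed overlap shares stayed above random placement, from 2.02% to 80.5%, though their sizes and order moved at equal list lengths. All 12 recomputed score differences kept their direction and passed the test, though sizes moved. The replicate 2 MACS difference of 212 became 27.5 for peaks in at least 1 other replicate. The replicate 3 MACS difference of 35.2 became 123 with 50% of both intervals shared. Keeping the better 50% of each list left, by construction, 5175, 13701 and 20028 MACS peaks and 4629, 5158 and 2109 HOMER peaks in replicates 1, 2 and 3; covered length moved by more than the spread between replicates for the replicate 3 MACS list (6.93 Mb) and the replicate 2 HOMER list (1.49 Mb). The 855 common intervals became 905 to 2744 when a replicate was left out, the highest without replicate 3, and 1593 without the replicate 3 MACS list alone. MACS lists alone gave 2137 and HOMER lists alone 1797, since fewer lists had to overlap. Asking for 50% of each 500 bp interval in every list gave 0, because HOMER peaks are narrower than that in replicates 1 and 3; this setting says nothing about stability. Of 73 recomputed L to S ratios, 70 kept their direction and side of the threshold. Most left out 1 chromosome pair. In MACS replicates 1 and 3 and HOMER replicates 1 and 2 all 9 pairs shared a sign. There these settings had to pass (exact adjusted p = 0.0134), so they say nothing about stability. MACS peaks of all 3 replicates in place of common regions gave 0.0073 (exact adjusted p = 0.836), counted as kept since neither passed. The replicate 2 MACS ratio shrank to -0.0060 (exact adjusted p = 0.887) in the better 50% of its list. That ratio, -0.07 in the full list, passed without chromosome pair 1 or pair 3 (-0.081 and -0.082, exact adjusted p = 0.0417 and 0.0312), and the ratio for common regions passed when HOMER peaks of all 3 replicates took their place (0.22); the cause was not tested. Spacing kept its call in all 5 settings. The share of replicate 3 HOMER peaks in their own MACS list minus the highest in another was -28.4 percentage points at 1 bp. It was -26.3 with centres within 200 bp and -0.996 with 50% of both intervals shared. The last rule depends on peak width as well as position, and the cause was not tested. In the better 50% of the replicate 2 MACS list, HOMER calls rose to 4.85% of peaks shared with replicate 3 alone and 93.2% of those shared with replicate 1 alone, a move beyond counting error in the same direction. No paired analysis was possible because the input libraries have no values of their own here. Motifs, gene positions, gene lists, L and S gene pairs and motif rate by reproducibility were not run, with all their alternatives, for want of a genome of the lists' build in the sources used here. Unknown depth limits every list length.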

Other observations

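The spacing and the tests of chance, weak peaks, exchanged lists and chromosome extent given here were chosen after the results were seen; those of input signal, another library and HOMER-called peaks on L and S chromosomes were written before their results.

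β-catenin regions common to all lists often lay close together. Of the 768 regions, 115 (15.0%) had another within 10 kb, against 0.580% after random placement, a 25.8-fold excess (permutation p = 0.002, the smallest that 1000 placements could give). Within 50 kb the share was 34.2% against 2.84%. Leaving out chromosome 7L gave 14.4% within 10 kb against 0.569%. Closeness was not particular to the common regions. Within 10 kb it was 19.6% against 1.39% for HOMER peaks found in all 3 replicates (permutation p = 0.002). For MACS peaks shared by replicates 2 and 3 alone without a HOMER peak it was 21.8% against 7.67% (permutation p = 0.002). Some neighbours nearly touched, such as 9_10L 71230683 to 71231182 and 71231290 to 71231789, and were counted as separate regions. In all, 32 groups of 3 or more regions within 50 kb of a neighbour held 123 regions. Random placement ignored mappability and the positions of genes.

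The largest group held 9 regions over 68.1 kb on chromosome 7L, from 21797753 to 21865873, and included 1 of the 10 best-ranked regions. A group on 3L from 136452410 to 136500110 held 6 regions. Groups of 5 lay on 7L from 112281952 to 112334231, on 9_10L from 43181238 to 43242718 and on 9_10S from 62124298 to 62188151. These 5 groups were chosen by size after their values were seen.

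In replicates 1 and 3, some of the highest scores belonged to peaks found in no other replicate's list of the same caller. The top MACS score of replicate 1, 3100, was shared by 4 peaks, among them 9_10L from 11504044 to 11505214, 9_10L from 27214113 to 27216089 and 9_10S from 10342491 to 10343520. Each was in 0 other MACS lists and in 1 HOMER list. For the peak at 27214113 that was the HOMER list of replicate 1. For the others the replicate of the HOMER list was not recorded. A wide MACS peak on 8L recurred, with 8713 bp from 99818593 to 99827305 in replicate 2 and 8710 bp from 99818592 to 99827301 in replicate 3. It scored 3100 in both lists and had no HOMER peak in any list. In the replicate 3 HOMER list, the top peak, on Scaffold34108 from 248 to 493 with a score of 149, and the third, on Scaffold24859 from 424 to 625 with a score of 109, were in 0 other lists. Peaks that share the value 3100 are not ordered by it. These peaks were chosen after their values were seen.

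The first pattern weighed is the set of MACS regions shared by replicates 2 and 3 with few HOMER calls in any replicate. Few calls were not particular to this set, since replicate 3 MACS peaks in no other MACS list had them in 0.472%. Chance overlap of long, randomly placed lists is argued against. Of the replicate 2 MACS peaks without a HOMER peak in any replicate, 48.4% were found in replicate 3. Random placement gave 1.76% and at most 1.99% in 1000 placements (permutation p = 0.002). The full replicate 2 list had already shown 42.5%, so this outcome was foreseeable and adds little. Random placement ignored mappability, so overlap from shared mappable sequence is not addressed. Low MACS scores in replicate 2 are argued against only as the whole cause. Peaks shared with replicate 3 alone had a HOMER peak in 3.66%. Peaks of the same score decile in no other MACS list had one in 26.9%, a difference of -23.3 percentage points (permutation p = 1e-05). Its direction could be foreseen from the unmatched 3.66% and 17.2%. Low scores may still contribute. Shared peaks without a HOMER peak had a median score differing by -29.0 from all HOMER-called peaks (permutation p = 1e-05). From HOMER-called peaks of the same sharing class it differed by -44.7 (permutation p = 1e-05). By replicate 3 scores, low scores as the whole cause stay open. The matched difference was 3.1 percentage points (permutation p = 1e-05). The score difference was 22.5 against all HOMER-called peaks but 3.65 within the shared peaks (permutation p = 0.404). Enrichment that is also present in the inputs may contribute and stays open, with 0 input libraries having values here, and no biological explanation was tested, since all 3 replicates are 1 group.

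The second pattern is that replicate 3 HOMER peaks lay less often in their own MACS list than in the best other one. The difference was -28.4 percentage points at 1 bp and -26.3 with centres within 200 bp. With 50% of both intervals shared it was -0.996, and replicate 2 HOMER peaks also lay more often in another replicate's MACS list (30.5% against 28.7%). HOMER peaks cannot share 50% of a much wider MACS peak, so that rule cannot separate position from peak width. The replicate 3 MACS list is the longest, and the 10351 best-scoring peaks of the MACS lists of replicates 1, 2 and 3 held 58.4%, 51.3% and 13.7% of these HOMER peaks. An exchange of lists with another replicate is argued against, since in 0 cases, over the other 2 HOMER lists and 3 overlap rules, did a HOMER list overlap the replicate 3 MACS list more than its own. Another library or input in the replicate 3 MACS run could give such lists and stays open, with 0 libraries having read counts in the files. No biological explanation was tested.

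The third pattern is the opposite L and S excess of the replicate 3 lists, HOMER being denser on L and MACS on S. Mappability or extent of the chromosomes could act alike on all lists of a caller. As the whole cause this is argued against by the ratios already given, 0.13 for MACS replicate 1 and -0.22 for MACS replicate 3. They differed by 0.35 ± 0.14, in 9 of 9 pairs (exact sign-flip p = 0.00391). The sign and p of this difference followed from those ratios, so the test adds no evidence beyond them. An effect of mappability that differs between lists stays open. MACS peaks of replicate 3 with a HOMER peak had a mean log2 ratio of 0.023 (exact sign-flip p = 0.695) and those without one -0.23. The paired difference was 0.26 ± 0.20, in 9 of 9 pairs (exact sign-flip p = 0.00391). As a description, the S excess thus lay in the peaks without a HOMER call, which are 38132 of the 40056. Whether the lack of a call explains the excess stays open. Peaks with a call were selected by lists that are denser on L, so the split cannot decide it. No biological explanation was tested.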
